A study of Mus musculus with 2 samples.

How the data were processed

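RNA was measured in 2 pools of cells sorted from mouse embryos at embryonic day 9.5. Per the labels, a Cre recombinase expressed from Grhl3 switched a membrane reporter from red to green fluorescence, so that green cells mark the non-neural ectoderm. The GFP-positive pool was labelled as non-neural ectoderm, and the RFP-positive pool as the neural tube cells that remained. Tissue other than the neural tube was dissected away before sorting, and RNA from 25 embryos of 21 to 25 somites was pooled. Libraries were made from 1 µg of total RNA with a TruSeq kit, per the labels' protocols. Each pool gave 1 library, so there were no replicates and p-values compare 2 libraries, not 2 cell populations.

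Per the submitters' processing notes, the tools were TopHat 1.3.2, Cufflinks 2.0.2 and Cuffdiff, and the genome build was mm9. The transcript annotation, the version of Cuffdiff and its settings are not given in the sources used here. The processed data were a single Cuffdiff table with 1 row per transcript, named by UCSC-style IDs. The authors deposited a log2 fold change for each transcript, and placeholder values at the limit of the number format marked ratios against 0. The test statistic is a score that the authors deposited beside each fold change. The p-value and q-value of each transcript are those the authors deposited. Cuffdiff's status column marks a transcript as tested ("OK"), as not tested, or as having too little data, too much data or a failed estimate.

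The table limited the analysis in 2 ways. First, it names its conditions only as q1 and q2, which match neither sample's labels. The 2 columns of abundance per condition were therefore not used, and no difference was given a direction between the GFP-positive and RFP-positive pools. Fold changes are those of condition q2 against condition q1. They are called positive or negative, as the authors' deposited table signs them. Second, the table's column for gene symbols names no gene in any row, so the files do not pair IDs with gene names. The gene tables used here are of a later build and list no IDs of this kind, so 0 of the 55418 IDs could match; this says nothing about the IDs themselves. The analysis planned before the data were examined covered 32 gene lists, a check of Grhl3, a bound on cross-contamination and a size rule on FPKM. None of these was run, because the transcripts have no gene names and abundance columns matched to no sample were not used. The rule planned for naming genes could not be followed for the same reason. The 2 positive and the 2 negative calls with the largest finite fold changes are named instead, by a rule set after the data were examined.

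From the deposited columns, transcripts were counted by status, call, sign and size. A call is a transcript marked significant in the authors' deposited table. For sizes, tested transcripts with a finite fold change were counted at 2-fold and 4-fold. The error of a log2 fold change was taken as its size divided by the size of its test statistic. Transcripts that share a locus string in the table were treated as one locus. Coordinates are on mm9 as the file gives them, and whether starts count from 0 or 1 is not stated there. Neighbouring called loci were those with a gap of at most 50000 bases and no overlap. Their number was set against 10000 random sets of tested transcripts of the same size, as a description, since transcripts are not replicates, and against 10000 sets of loci matched on how many list a single transcript. The Benjamini-Hochberg adjustment and the neighbour count were tested on simulated data before use. With 29405 simulated statistics, 58.0% of 100 shifts of 4 and 100.0% of 100 shifts of 6 standard errors were recovered. The simulated statistics were drawn from a standard normal distribution, which the deposited p-values did not follow. These rates therefore do not give the power of the authors' test. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The depth of the libraries is unknown from the columns used, so no counting intervals or floors are given.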

Results

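The data compare the transcriptome of the non-neural ectoderm with that of the remaining neural tube cells at the stage of neural tube closure. The non-neural ectoderm is the sheet of surface cells that flanks the closing neural tube. Grhl3, which drives the Cre used for sorting, encodes an epithelial transcription factor. There was 1 library of GFP-positive cells and 1 of RFP-positive cells. The comparison was deposited as fold changes and tests between 2 conditions that are not matched to the pools. The transcripts carry IDs without gene names. What follows therefore gives the number, size and position of the differences between the 2 conditions, and not which pool was higher or which genes they were.

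The authors' deposited table held 55418 transcripts at 24214 loci. Of these loci, 12735 listed 1 transcript and 11479 listed several. The authors tested 29405 transcripts, or 53.1%. A further 25431 transcripts, or 45.9%, were left untested, 337 had too little data, 244 had a failed estimate and 1 had too much data. Among the tested transcripts, 28140 had a finite fold change, and 1265 had a ratio against 0. The ratios against 0 were positive for 494 transcripts and negative for 771.

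Most tested transcripts with a finite fold change differed little between the conditions. Their median log2 fold change was 0.0046, with quartiles of -0.25 and 0.28. Of these 28140 transcripts, 24381, or 86.6%, lay within 2-fold. The 1265 ratios against 0 are not part of these values. At least 2-fold differences were positive for 2155 transcripts and negative for 1604, which made 57.3% of them positive. Among transcripts with an error of at most 0.6 log2 units, 225 were at least 2-fold positive and 91 at least 2-fold negative, or 71.2% positive. The median error of a log2 fold change was 0.89 over all tested transcripts with a finite value, close to the size of a 2-fold difference.

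In the authors' deposited table, 236 transcripts at 230 loci were called different, or 0.803% of those tested. Positive calls were 203 of the 236, or 86.0%, and negative calls were 33. In this table, 6 calls were ratios against 0, of which 2 were positive and 4 negative. The 201 positive calls with a finite value had a median log2 fold change of 2.88, a 7.35-fold difference, with quartiles of 2.40 and 3.21. The 29 finite negative calls had a median of -2.38, a 5.20-fold difference, with quartiles of -2.80 and -2.04. The median error of a call was 0.49 log2 units for the positive and 0.57 for the negative calls. At least 4-fold differences made up 172 of the positive and 23 of the negative finite calls. The highest q-value among the calls of the authors' deposited table was 0.0489. Because each pool gave 1 library, this test has no replicate check.

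**Figure D1:**
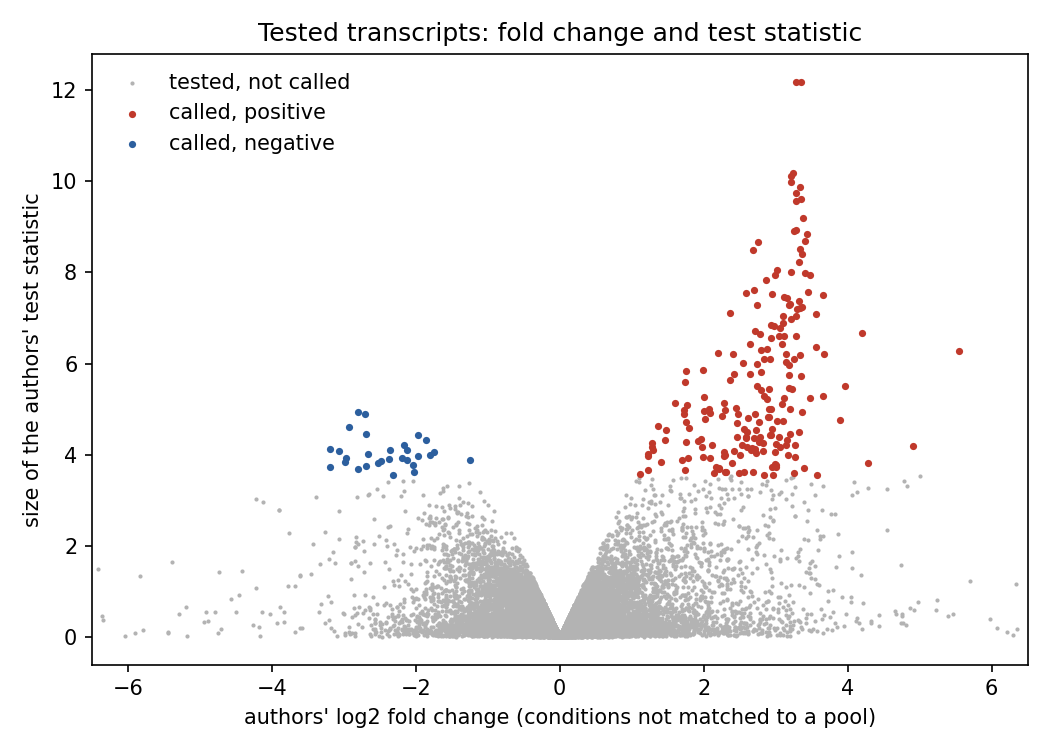
Each point is 1 tested transcript with a finite fold change. The authors' log2 fold change is on the x axis and the size of their test statistic on the y axis. The 230 finite calls are plotted, and the 6 calls that are ratios against 0 are not. Red points are positive calls, blue points negative calls and grey points transcripts without a call. The 18 calls with p listed at 0 lie between 2.69 and 3.43, and 390 transcripts without a call lie outside the plotted range of 6.5 on either side.

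Of the 201 finite positive calls, 130, or 64.7%, had a log2 fold change between 2.5 and 3.5, and 12 lay above 3.5. The 50 positive calls with the largest test statistics had a median of 3.25, a 9.53-fold difference, an interquartile range of 0.32 and a full range from 2.37 to 4.21. Their median error was 0.40. Of all finite positive calls, 26 lay below that median by over 3 times their own error and 0 lay above it by as much. This split does not show an upper limit. At a given test statistic, the error as defined here grows with the fold change, so an excess above the median is harder to reach. The median itself came from calls chosen by their test statistics. The 18 calls with a p-value listed at 0 in the authors' deposited table were all positive and lay between 2.69 and 3.43. The negative calls reached -3.20.

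The largest finite positive call was transcript uc007cnn.2 on chromosome 1, from 133534890 to 133572084 of mm9. Its log2 fold change in the authors' deposited table was 5.55 with an error of 0.88, and its q-value there was 1.70e-07. The next was uc008qqi.1 on chromosome 3, from 98656119 to 98663717, at 4.91 with an error of 1.17 and a q-value of 0.0050 in the authors' deposited table. The largest finite negative call was uc007xwy.1 on chromosome 15, from 102784956 to 102787132. The authors' deposited table gave it a log2 fold change of -3.20, with an error of 0.78 and a q-value of 0.00641. It was followed by uc009cme.1 on chromosome 6, from 83018318 to 83020219, at -3.19 with an error of 0.86 and a q-value of 0.0264 in the authors' deposited table. The annotation of these loci on mm9 was not used here, so whether they are coding is not stated. Of the 4, uc007xwy.1 was the only transcript listed for its locus, and the others shared their locus with at least 1 more.

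Calls were found on every autosome and on chromosome X. Chromosome 2 held 27 calls, the most of any, of which 19 were positive and 8 negative. Chromosome 15 had the highest share, with 17 calls among 1170 tested transcripts, or 1.45%. On chromosome 10 the share was lowest among the autosomes, with 3 calls among 1381 tested, or 0.217%. None of the 8 tested transcripts on chromosome Y was called. Whether these shares differ beyond chance was not tested, since transcripts of one locus are not independent.

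Some calls lay in runs of neighbouring loci. On chromosome 11, from 32176599 to 32197310, all 4 tested transcripts were positive calls, with log2 fold changes between 3.19 and 3.36. On chromosome 7, from 110961037 to 110991676, 4 of 5 tested transcripts were positive calls, between 3.12 and 3.40. On chromosome 2, from 74506366 to 74533159, all 4 tested transcripts were negative calls, between -2.80 and -2.04. On chromosome 15, from 78075240 to 78184277, 3 of 7 tested transcripts were positive calls, between 2.82 and 3.34. Whether members of these runs share reads was not examined.

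**Figure D2:**
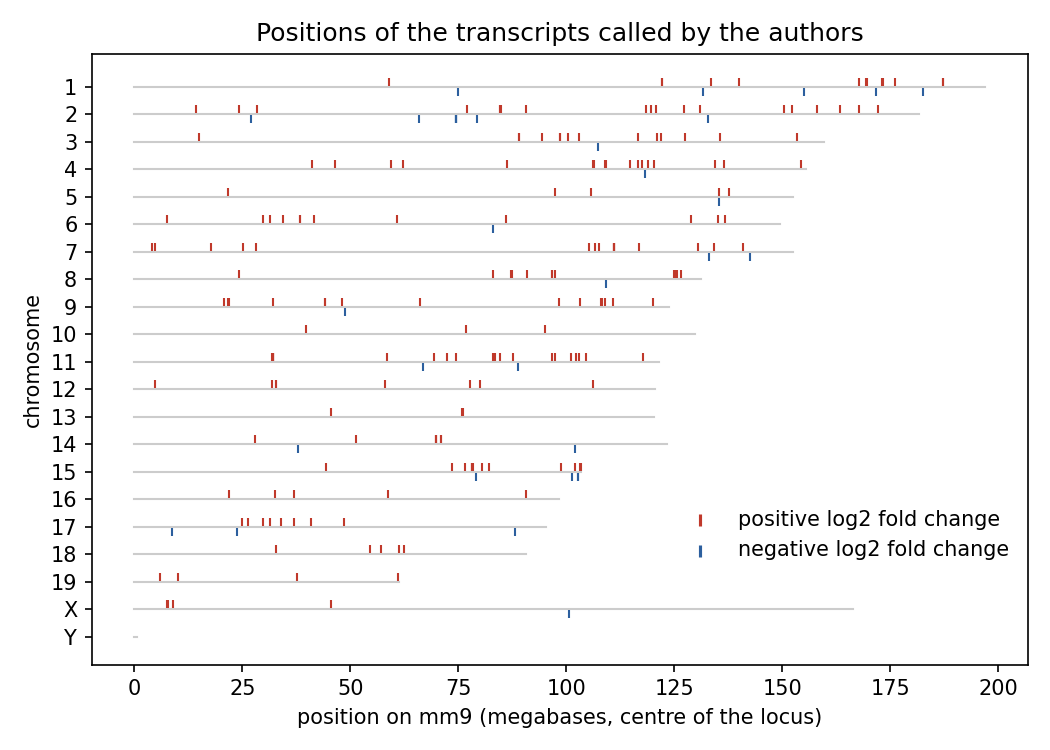
Each tick is 1 transcript called in the authors' deposited table, at the centre of its locus on mm9 in megabases on the x axis, with 1 row per chromosome. Red ticks above the line are the 203 positive calls, blue ticks below it the 33 negative calls, and each grey line ends at the last tested locus.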

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

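With 1 library per pool, no replicate could be left out, and the other settings planned before the data were examined (pseudocounts, filters on low values, scalings of the abundances, gene lists and the cross-contamination bound) were not run, because the abundance columns, matched to no sample, were not used here and the transcripts have no gene names. The 2 planned settings that were run are the 4-fold rule and centring on the median, and all others were chosen after seeing the data. The 236 calls ranged from 184 at a q-value of at most 0.01 to 279 at a q-value of at most 0.1 in the authors' deposited table. Adjusting the deposited p-values over all rows gave 215. At a q-value of at most 0.01, negative calls numbered 16 in place of 33. Counting only loci that list a single transcript left 107 calls, 86 positive and 21 negative. These were 2.54% of the 4207 tested transcripts at such loci, against 0.512% at loci that list several. Positive calls made up between 80.4% and 91.3% of the calls under every alternative run. The counts of at least 2-fold differences depended more on the rule. The 4-fold rule gave 916 positive and 485 negative transcripts, loci with a single transcript gave 219 and 191, and an error of at most 0.6 gave 225 and 91. Counting every status raised both signs, to 3197 positive and 2586 negative. Centring on the median moved the counts to 2144 and 1620. The positive share of these differences lay between 52.7%, with ratios against 0 counted, and 71.2%, with an error of at most 0.6. Library depth was not known, so what it limits could not be given beyond the authors' own marking of 45.9% of transcripts as not tested.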

Other observations

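The tests of the first pattern were fixed before their results were seen, the one on opposite signs after the other tests had been run, and the tests of the other patterns were chosen only after the result was seen.

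The largest finite fold changes in the table mostly had no call. Of the tested transcripts with a finite absolute log2 fold change of at least 5, 414 had no call and 1 had one. The 1265 tested ratios against 0, of which 6 were called, are not counted here. All 414, or 100%, lay at loci that list several transcripts, against 85.1% of all tested transcripts with a finite value. A tested transcript of the opposite sign lay at the same locus for 78.0% of them, against a median of 58.0% and a central 95% range of 53.9% to 62.1% in 10000 random sets matched on the number of tested transcripts at the locus. Both values are consistent with abundance split between overlapping transcripts of one locus, with reads moved from one transcript of a locus to another, though 42 of the 414 had no other tested transcript at their locus. A real switch between transcripts stays open, since it would appear in the same way. The range of 53.9% to 62.1% came from transcripts drawn independently. Several of the 414 can lie at one locus, so this range may be too narrow.

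The positive calls had a median log2 fold change of 2.88 and the negative calls one of -2.38, with quartiles of 2.40 and 3.21 against -2.80 and -2.04. The positive calls ranged from 1.11 to 5.55 and the negative calls from -3.20 to -1.25, and no test of spread was run. Among transcripts with an error of at most 0.6, called or not, the numbers from 2 to 2.5, 2.5 to 3, 3 to 3.5 and 3.5 to 4 were 27, 37, 49 and 4 on the positive side, and 8, 2, 0 and 0 on the negative side. Selection by the test statistic stays open. From a log2 fold change of 2.5 upwards, an error of at most 0.6 already requires a test statistic large enough for a call. The counts from 2.5 upwards are therefore selected by the statistic and cannot tell selection apart. The excess of 12 transcripts from 3 to 3.5 over those from 2.5 to 3 was also within the counting spread. The 12 finite positive calls above 3.5 had a median error of 0.71, wider than the 0.6 allowed in these counts. The limit left out larger negative calls too, since their lower quartile was -2.80. The 2 largest negative calls, at -3.20 and -3.19, had errors of 0.78 and 0.86. The low negative counts from 2.5 upwards are therefore partly set by the limit on the error. One source of RNA at a fixed ratio between the conditions, such as a cell population that entered one pool more than the other or carry-over between the pools in the sort, might also set an upper limit on the positive side, and 0 of 201 positive calls exceeded the median of the 50 strongest by over 3 errors. The largest excess was 2.60 errors, and the errors above the limit are too wide to decide. Which source it would be was not tested. The transcripts have no names here, and their positions, which could be looked up, were not compared with an mm9 annotation. The difference between the sorted populations themselves also stays open.

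Called transcripts lay next to each other more often than random sets did. There were 18 pairs of neighbouring called loci without overlap, in 11 groups, against a median of 5 and a highest value of 16 in 10000 random sets of tested transcripts. Calls lay more often at loci with a single transcript than tested transcripts did, but 10000 random sets of loci matched on this had a median of 4 and at most 13 pairs, against the observed 18, so it does not account for the runs. Near-identical neighbouring genes that share reads and neighbouring genes that are regulated together both stay open, and neither was tested. In 1 of the 11 groups, on chromosome 5 from 135390119 to 135422804, neighbouring calls went in opposite directions, at 3.19 and -2.48.

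The p-values in the authors' deposited table were skewed towards 1. Of the tested transcripts, 3.10% had a p-value under 0.05 in the authors' deposited table, and 19.6% had one over 0.95. Every one of the 28140 finite tested fold changes had a test statistic of the opposite sign. The signs given here are those of the fold changes. Adjusting the deposited p-values over the tested transcripts again gave 236 calls.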
